A study of Arabidopsis thaliana with 12 samples.

How the data were processed

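Total RNA from plants of the genotypes flu/ex1 and flu/ex1/ydl1 was extracted with Trizol and sequenced from Illumina TruSeq libraries, per the labels' protocols. The deposited values are raw read counts per locus, 1 file per sample with 36917 loci, and their unit was checked as whole numbers whose totals differ between samples. Per the labels, the authors trimmed reads with Trimmomatic, checked them with FastQC, aligned them to the genome build TAIR10 with TopHat2 2.1.1 and counted them with featureCounts. The annotation, the strand setting and the treatment of reads that map to several loci are not stated, so values of paralogs and of overlapping or antisense loci are uncertain. Gene names and the order of neighbouring loci come from a reference of the assembly TAIR10.1, in which 36632 of the 36917 loci were found and 285 were not, and no coordinates are given because the builds differ. The plastid has 133 of the loci and the mitochondrion 152.

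Each file was tied to its sample by the deposit's own record and each sample to its group by its labels. The time in the deposited file's name, which differs from the label for 8 of 12 libraries, was set up before the data were examined as the other way to group the libraries, as were the comparisons, the gene lists, the rule for naming genes and the test of pairings. Which alternatives to repeat with file-name times, the comparison of the 4 libraries with 1 time in both and the thinning were chosen after the data were seen.

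Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 17879, and scaled by TMM. The 6 groups of genotype and time were fitted together with edgeR 4.0.16 quasi-likelihood F tests in R 4.3.3, and the p-values of each of the 10 comparisons were adjusted by Benjamini-Hochberg with a threshold of 0.05. CPM were computed from the deposited counts with the TMM factors, and standard errors come from the fold change and its F statistic. A group with 0 counts was given a floor of 3 counts over the group, and folds against it are written as at least that many times. Such floors cover counting error only. FLU, EX1 and EX2 were named in every library. In each comparison the 10 largest rises and 10 largest falls were named among genes past the threshold with a mean of at least 1 CPM and no overlap between the groups, or all genes where 5 or fewer passed, or the 3 with the smallest p where none did, and up to 4 members of each list with the smallest p. For the difference between genotypes the condition on overlap was not used. The text gives a part of these genes.

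The 15 gene lists cover singlet oxygen-responsive genes, jasmonate, salicylate and immune response, heat shock, antioxidant and detoxification, tetrapyrrole synthesis, light harvesting and carbon fixation, light-induced genes, genes induced in darkness and starvation, the circadian clock, shade, touch with wounding and calcium, abscisic acid and drought, root markers, and seed storage. Of 256 genes 4 were dropped because the reference gives their locus another symbol, and 0 were missing from the files. No member of the seed storage list had enough counts to be tested. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, and beside it with camera at an estimated correlation and with fry, which asks whether the genes of a list move one way and does not compare them with other genes. The p-values were adjusted by Benjamini-Hochberg over the lists of a comparison. EDS1 is in both the singlet oxygen and the salicylate list.

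The test of pairings is exact and one-sided. It takes the root mean square difference in log2 CPM (prior count 2) over the 500 most variable genes within pairs, for each way to split the 6 libraries of each genotype into 3 pairs, and the smallest share it allows is 0.00444. Total counts, plastid share and 4 other library quantities were compared between genotypes by exact two-sided permutation tests with 6 libraries each. Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, nuclear genes only, only the groups compared, replicate number as a block, genotype alone, each library left out in turn and, for file-name times, libraries thinned to the lowest nuclear count. Where a library was left out, the lone library of its group was assumed to vary like those of the other groups. On simulated counts for 100 genes changed 2-fold and 100 changed 4-fold, the comparison of genotypes over all 12 libraries recovered 95% and 100% of them (17430 genes tested). The comparison of 60 with 0 min in flu/ex1/ydl1 recovered 29% and 98% (17495 genes tested). Where the simulated change followed the file names, that comparison recovered 21% and 97% with file-name groups (17535 genes tested), and 0% and 2% with labelled groups (17451 genes tested). All simulations took the spread between libraries from the fit with file-name groups and changed only genes above a set level. In the data, pairs by labelled time lay 1.96 log2 units apart against 1.06 by file-name time over the 500 most variable genes. Over all 17879 genes kept by the filter these distances were 0.729 and 0.592. The shares recovered with labelled groups may therefore be too high. With 1 of 14 lists changed in simulated data, camera and fry called that list and 0 others. Genes were simulated independently of each other, so this does not test the preset correlation.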

Results

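RNA was sequenced from 12 libraries of Arabidopsis thaliana plants of 2 genotypes, flu/ex1 and flu/ex1/ydl1. The flu mutant builds up protochlorophyllide in darkness, and light turns this pigment into a source of singlet oxygen in the plastid. EX1 is a plastid protein through which much of the nuclear response to that singlet oxygen runs. By the labels, plants were 6 d old, had spent 4 h in darkness and were collected at 0, 30 or 60 min of light, with 2 libraries in each of the 6 groups. The title of the series names the question, which is whether YDL1 holds back the changes in gene expression that singlet oxygen brings. The total count ran from 7859611 to 11591060 per library, of which 63.3% to 71.7% fell on plastid loci, and 17879 genes had enough counts to be tested. The labels do not say whether the libraries of a group come from separate plants or cultures, so each p measures only the spread between samples.

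FLU (AT3G14110) and EX1 (AT4G33630), the genes mutated in both genotypes, had counts in all 12 libraries. FLU, a negative regulator of chlorophyll synthesis, stood at 45.2 to 56.4 CPM in the 6 flu/ex1 libraries and 29.5 to 59.8 CPM in the 6 flu/ex1/ydl1 libraries. EX1 stood at 2.91 to 5.22 CPM in the 6 flu/ex1 libraries and 2.09 to 5.36 CPM in the 6 flu/ex1/ydl1 libraries. The means for FLU were 43.5 ± 9.95 CPM in flu/ex1/ydl1 against 50.7 ± 4.21 CPM in flu/ex1 (SD, n = 6 each), with an edgeR adjusted p of 0.505 over the 12 libraries. The means for EX1 were 3.22 ± 1.26 CPM in flu/ex1/ydl1 against 4.42 ± 0.797 CPM in flu/ex1 (SD, n = 6 each), with an edgeR adjusted p of 0.148. EX2 (AT1G27510), the close relative of EX1, averaged 8.55 ± 1.21 CPM in flu/ex1/ydl1 against 9.58 ± 1.5 CPM in flu/ex1 (SD, n = 6 each), with an edgeR adjusted p of 0.616. The mutations in FLU and EX1 are shared by both genotypes, so these levels do not check the genotype labels. The reference names no locus YDL1, so the level of that gene could not be read.

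For 8 of the 12 libraries the light time in the label differed from the light time in the deposited file's name, while the genotype was the same in both. In sample order, the labelled times of each genotype run 0, 0, 30, 30, 60, 60 min, and the times in the file names run 0, 30, 60, 0, 30, 60 min. The 4 libraries with the same time in both are flu/ex1 0 min replicate 2, flu/ex1 60 min replicate 3, flu/ex1/ydl1 0 min replicate 1 and flu/ex1/ydl1 60 min replicate 2. Because the times are in doubt, each comparison is given by the labels first and by the file names second, and libraries are called by their labels throughout. A value with ± after a gene's name is a log2 fold change with its SE unless CPM is written.

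Libraries that share a time in the file names resembled each other, and libraries that share a labelled time did not stand out. Over the 500 most variable genes, the mean distance within pairs was 1.96 log2 units for pairs by labelled time and 1.06 for pairs by file-name time, against a mean of 1.81 over all ways to pair the 6 libraries of each genotype. In an exact one-sided test, 127 pairings, the labelled one included, were as close as the labelled one (exact p = 0.564). That by file names was matched by 2 pairings, itself included (exact p = 0.00889). STZ and WRKY33, transcription factor genes of the singlet oxygen response, show the same arrangement per library. STZ in flu/ex1/ydl1 averaged 156 ± 46.3 against 10.6 ± 1.86 CPM (SD, n = 2 each) at 60 and 0 min by file-name time, while the 2 libraries labelled flu/ex1/ydl1 30 min had 189 and 9.29 CPM.

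**Figure D1:**
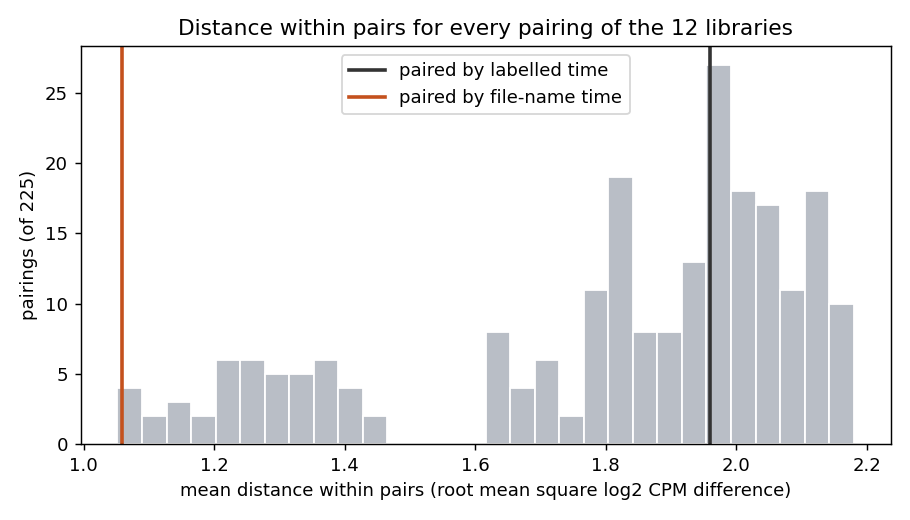
The x axis gives the mean distance within pairs in log2 CPM and the y axis the number of pairings at that distance, with vertical lines for the pairings by labelled time and by file-name time. The file-name line lies at 1.06, near the low end, and the labelled line at 1.96, inside the bulk.

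**Figure D2:**
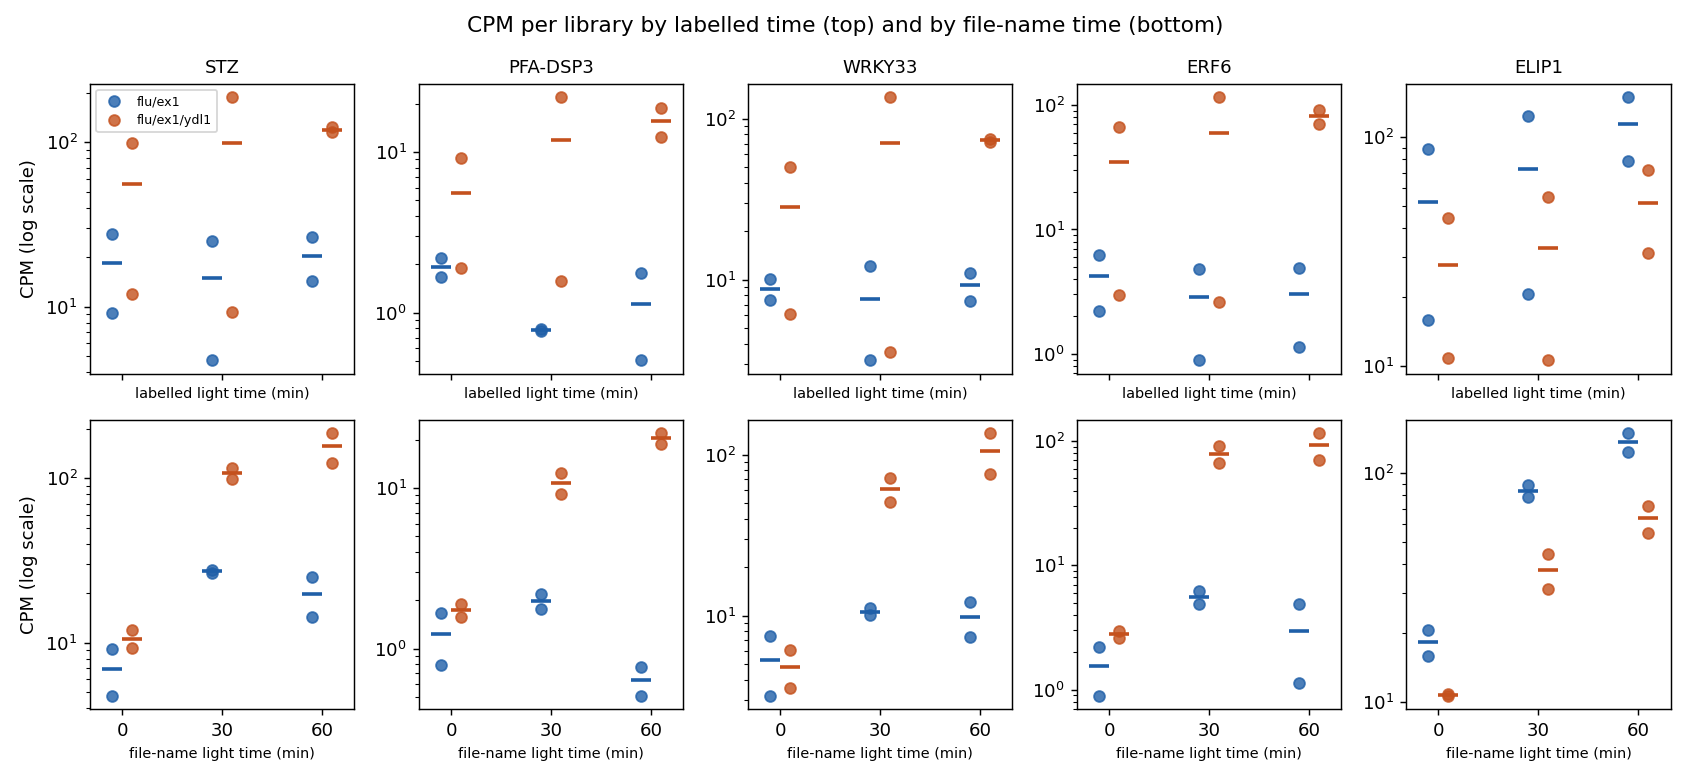
Each point is the CPM of STZ, PFA-DSP3, WRKY33, ERF6 or ELIP1 in 1 of the 12 libraries on a log y axis, against the light time in min from the labels (top) or the file names (bottom), with bars at the mean of each group of 2. By file-name time the first 4 genes reach their highest group mean in flu/ex1/ydl1 at 60 min, while by labelled time the 2 libraries of a group often lie far apart.

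The comparison of genotypes over all 12 libraries asks what the ydl1 mutation changes whatever the light time. With labelled times, 3 genes rose and 3 fell in flu/ex1/ydl1. CYCP3;2, a P-type cyclin gene, rose from 0.974 ± 0.467 to 2.95 ± 0.93 CPM (SD, n = 6 each), a log2 fold change of 1.66 ± 0.23 (SE) with an adjusted p of 0.0391. ZF3, a zinc finger gene, rose by 1.64 ± 0.22 (adjusted p = 0.0391) on the log2 scale and QWRF9 by 1.46 ± 0.19 (adjusted p = 0.0391). ZF3 (AT5G43170) and QWRF9 (AT5G43160) have adjacent locus numbers, so their rises may not be separate. Both differed more at labelled 60 min alone, by 3.45 ± 0.41 and 2.64 ± 0.34. AT3G63052 stood at 4.17 ± 3.57 against 356 ± 141 CPM (SD, n = 6 each), a log2 fold change of -6.61 ± 0.51 (SE) with an adjusted p of 0.00062, and MRD1 had a log2 fold change of -6.02 ± 0.44 (adjusted p = 0.00062). GID1B, a gibberellin receptor gene, had 3 counts against 248 over the 6 libraries of each genotype (adjusted p = 0.0028). None of the 17 tested singlet oxygen-responsive genes passed over all genes, 17 passed adjusted over the list alone, and their median log2 fold change was 2.68 (camera adjusted p = 6.79e-10, adjusted p = 0.563 with an estimated correlation). Adjusted over the list alone, 11 of 21 jasmonate, 11 of 13 salicylate, 6 of 10 heat shock, 12 of 14 touch and 1 of 22 antioxidant genes were higher in flu/ex1/ydl1, and 2 of 22 tetrapyrrole genes were higher and 2 lower. At an unadjusted p under 0.05 there were 3426 genes, and with the same labelled times DESeq2 called 774 genes, edgeR without the filter on low counts 1813, edgeR with genotype alone in the model 747 and edgeR with replicate numbers as a block 1. The edgeR count of 6 became 3 without flu/ex1 0 min replicate 3, flu/ex1 30 min replicate 2, flu/ex1 60 min replicate 3, flu/ex1/ydl1 0 min replicates 1 or 3 or flu/ex1/ydl1 60 min replicates 1 or 2, 19 without flu/ex1/ydl1 30 min replicate 1 and 1633 without flu/ex1/ydl1 30 min replicate 3.

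With times from the file names, genes of the singlet oxygen-responsive list were higher in flu/ex1/ydl1. Genes of the jasmonate, salicylate, heat shock and touch lists were higher too, and all libraries carry the flu mutation. A response to singlet oxygen can therefore not be told apart from another stress response here. Over the 12 libraries, 16 of 17 singlet oxygen-responsive genes rose, with a median log2 fold change of 2.16 (camera adjusted p = 9.73e-25, adjusted p = 0.11 with an estimated correlation, fry adjusted p = 0.00292). ERF6, an ethylene response factor gene, stood at 58.4 ± 46.6 against 3.36 ± 2.23 CPM (SD, n = 6 each), a log2 fold change of 3.24 ± 0.30 (SE) with an adjusted p of 4.69e-06. ERF5 rose by 2.80 ± 0.28 (adjusted p = 5.96e-06) on the log2 scale, PFA-DSP3, a phosphatase gene, by 2.66 ± 0.22 (adjusted p = 2.09e-06) and CNI1 by 2.90 ± 0.21 (adjusted p = 7.34e-07). Of jasmonate genes 12 of 21 (13 adjusted over the list alone) rose, among them LOX4, a lipoxygenase gene, by 2.05 ± 0.23 (adjusted p = 2.04e-05). Of salicylate genes 8 of 13 (11 adjusted over the list alone) rose, as did 5 of 10 (7) heat shock, 7 of 22 (8) antioxidant and 9 of 14 (12) touch, wounding and calcium genes. The camera calls of these lists had adjusted p = 0.179, 0.11, 0.218, 0.179 and 0.11 with an estimated correlation. In tetrapyrrole synthesis FC1, a ferrochelatase gene, rose by 1.54 ± 0.16 (adjusted p = 1e-05), HEMA2, a glutamyl-tRNA reductase gene, rose by 1.29 ± 0.20 (adjusted p = 0.000387), and CHLI1, a magnesium chelatase gene, had -0.60 ± 0.18 (adjusted p = 0.0433). The light-induced genes ELIP1 and ELIP2 had log2 fold changes of -1.01 ± 0.15 (adjusted p = 0.000316) and -0.58 ± 0.15 (adjusted p = 0.019), and AT3G63052 of -6.51 ± 0.41 (adjusted p = 3.33e-07). None of 20 light harvesting, 17 clock, 3 shade and 3 root marker genes passed. In all 1604 genes passed, 1252 higher and 352 lower. The count was 1023 without flu/ex1/ydl1 0 min replicate 1.

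The comparisons of genotypes at each time ask when the ydl1 mutation matters. At 0 min by the labels, MRD1 had 0 counts over the 2 flu/ex1/ydl1 libraries against 144, at least 42.6-fold lower, and AT3G63052 fell by 8.13 ± 0.96 on the log2 scale (adjusted p = 0.0299). These were the 2 genes that passed with edgeR, against 4 with DESeq2, 166 without the filter on low counts, 1 on only the groups compared and 0 with replicate numbers as a block. The edgeR count was 0 without flu/ex1 0 min replicates 2 or 3, flu/ex1 30 min replicates 2 or 3, flu/ex1 60 min replicates 1 or 3 or flu/ex1/ydl1 0 min replicates 1 or 3. No gene passed at 30 min by the labels with edgeR, where AT3G63052 had -5.95 ± 0.85 (adjusted p = 0.246), MRD1 -4.35 ± 0.61 (adjusted p = 0.246) and GID1B 1 count against 80. Of all genes 1210 had an unadjusted p under 0.05, DESeq2 called 2, edgeR without the filter on low counts 833 and edgeR on only the groups compared 0. The edgeR count was 830 without flu/ex1/ydl1 30 min replicate 3. No gene passed at 60 min by the labels with edgeR, where ZF3 had 3.45 ± 0.41 (adjusted p = 0.0618), QWRF9 2.64 ± 0.34 (adjusted p = 0.0692) and AT3G63052 -5.75 ± 0.85 (adjusted p = 0.126). Of all genes 3188 had an unadjusted p under 0.05, DESeq2 called 312, edgeR without the filter on low counts 1537 and edgeR on only the groups compared 1511. The edgeR count was 924 without flu/ex1/ydl1 30 min replicate 1 and 930 without flu/ex1/ydl1 30 min replicate 3. Of the 17 singlet oxygen-responsive genes 0 passed over all genes at 30 or 60 min by the labels, and 14 and 15 did adjusted over the list alone. Their medians were 3.19 and 3.37 (camera adjusted p = 5.58e-09 and 6.33e-09, adjusted p = 0.697 and 0.638 with an estimated correlation).

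With times from the file names, 2 genes differed between the genotypes at 0 min: AT3G63052 had -6.42 ± 0.71 (adjusted p = 0.00122) and MRD1 3 counts against 104 (adjusted p = 0.0339), and 0 of 17 singlet oxygen-responsive genes passed. The 20 light harvesting genes had a median of 0.42 with 0 passing (camera adjusted p = 0.000116, adjusted p = 0.698 with an estimated correlation). The count at 0 min was 10 without the filter on low counts and 1 with the file-name replicate block. It was 0 without flu/ex1/ydl1 0 min replicate 1, 1 without flu/ex1 0 min replicates 2 or 3, flu/ex1 30 min replicate 2, flu/ex1 60 min replicate 1 or flu/ex1/ydl1 30 min replicate 3 and 4 without flu/ex1/ydl1 30 min replicate 1.

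At 30 min by the file names, 700 genes passed, 637 higher and 63 lower in flu/ex1/ydl1. Of singlet oxygen-responsive genes 16 of 17 (16 adjusted over the list alone) were higher, with a median of 2.49 (camera adjusted p = 3.65e-24, adjusted p = 0.118 with an estimated correlation). ERF13 stood at 75.9 ± 21.2 against 3.66 ± 0.604 CPM (SD, n = 2 each), a log2 fold change of 4.37 ± 0.65 (SE) with an adjusted p of 0.00088. ERF6 was higher by 3.83 ± 0.47 (adjusted p = 0.00031), MPK3, a stress-activated protein kinase gene, by 2.82 ± 0.32 (adjusted p = 0.000213), and FC1 by 2.05 ± 0.28 (adjusted p = 0.00051) on the log2 scale, while ELIP1 had -1.14 ± 0.26 (adjusted p = 0.0177). Among touch, wounding and calcium genes 9 of 14 (10 adjusted over the list alone) were higher, and among salicylate genes 4 of 13 (11 adjusted over the list alone). Their camera calls had adjusted p = 0.149 and 0.118 with an estimated correlation. AT3G63052 had -7.51 ± 0.76 (adjusted p = 0.000107) and GID1B 1 count against 81. The count at 30 min was 121 without flu/ex1 60 min replicate 1, 173 without flu/ex1/ydl1 60 min replicate 1 and 314 without flu/ex1 0 min replicate 3.

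At 60 min by the file names, 1763 genes passed, 1525 higher and 238 lower in flu/ex1/ydl1. All 17 of 17 tested singlet oxygen-responsive genes were higher, with a median of 3.85 (camera adjusted p = 9.99e-27, adjusted p = 0.0602 with an estimated correlation). PFA-DSP3 stood at 20.4 ± 2.33 against 0.639 ± 0.19 CPM (SD, n = 2 each), a log2 fold change of 4.99 ± 0.35 (SE) with an adjusted p of 6.94e-07. ERF6 was higher by 4.98 ± 0.50 (adjusted p = 5.15e-06), LOX4 by 3.66 ± 0.39 (adjusted p = 9.06e-06), and HSP101, a heat-induced chaperone gene, by 3.42 ± 0.44 (adjusted p = 3.85e-05) on the log2 scale. Of jasmonate genes 16 of 21 (17 adjusted over the list alone) were higher, as were 10 of 13 (11) salicylate, 8 of 10 (9) heat shock, 13 of 22 (13) antioxidant and 12 of 14 (14) touch genes. The camera calls of these lists had adjusted p = 0.0617, 0.0602, 0.0738, 0.0602 and 0.0602 with an estimated correlation. FC1 and HEMA2 were higher by 2.77 ± 0.29 (adjusted p = 7.08e-06) and 2.78 ± 0.33 (adjusted p = 2.11e-05), and ELIP1 had -1.11 ± 0.26 (adjusted p = 0.00838). Most tetrapyrrole genes went the other way in the 4 libraries with 1 time in both. There 17 of 22 were lower in flu/ex1/ydl1 at 60 min and 5 higher, with a median log2 difference of -0.53 and no test. GID1B had 1 count against 127 and MRD1 2 counts against 177. The count at 60 min was 942 without flu/ex1 60 min replicate 3.

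The comparisons of 30 and 60 min with 0 min in flu/ex1 ask what light changes where EX1 is mutated and YDL1 is not. By the labels no gene passed at 30 min with edgeR, where AT3G01845 had -1.39 ± 0.31 (adjusted p = 0.958), AT4G34345 3.07 ± 0.69 (adjusted p = 0.958) and the ribosomal RNA locus AT3G41768 -6.25 ± 1.41 (adjusted p = 0.958). Ribosomal RNA loci took 0.828% of the counts of flu/ex1 0 min replicate 2 and at most 0.0458% of those of any other library. Of all genes 701 had an unadjusted p under 0.05, DESeq2 called 0, edgeR without the filter on low counts 23 and edgeR on only the groups compared 0. By the labels no gene passed at 60 min with edgeR, where ZF3 had -2.28 ± 0.41 (adjusted p = 0.643), CYCP4;2 -2.26 ± 0.46 (adjusted p = 0.643) and AT5G61660 -2.22 ± 0.46 (adjusted p = 0.643). CYCP4;2 (AT5G61650) and AT5G61660 have adjacent locus numbers, so their falls may not be separate. Of all genes 1363 had an unadjusted p under 0.05, DESeq2 called 6, edgeR without the filter on low counts 90 and edgeR on only the groups compared 52. The edgeR count was 1 without flu/ex1 0 min replicate 3. The 15 light-induced genes had a median of 0.97 at 60 min by the labels (camera adjusted p = 0.00277, adjusted p = 0.977 with an estimated correlation).

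By the file names, genes of the light and clock responses rose in flu/ex1 at 30 min. Of light-induced genes 4 of 15 (10 adjusted over the list alone) rose (camera adjusted p = 2.84e-20, adjusted p = 0.00798 with an estimated correlation). ELIP1, which encodes an early light-induced chlorophyll-binding protein, went from 18.3 ± 3.37 to 83.4 ± 7.11 CPM (SD, n = 2 each), a log2 fold change of 2.18 ± 0.27 (SE) with an adjusted p of 0.00104. SIGE, a plastid sigma factor gene, rose by 2.54 ± 0.36 (adjusted p = 0.0024), HY5, a light-signalling transcription factor gene, by 1.62 ± 0.27 (adjusted p = 0.00699) and ELIP2 by 1.29 ± 0.26 (adjusted p = 0.026) on the log2 scale. Of clock genes 4 of 17 (5 adjusted over the list alone) rose (adjusted p = 0.0395 with an estimated correlation). They were AT5G64170 (LNK1), with 3.14 ± 0.39, PCL1 (LUX), PRR9 by at least 19.5-fold from 0 counts, and GI with 39 counts against 2. Of singlet oxygen-responsive genes 1 of 17 (5 adjusted over the list alone) rose, STZ by 1.99 ± 0.35 (camera adjusted p = 2.04e-09 for the list, adjusted p = 0.186 with an estimated correlation). NCED3, an abscisic acid synthesis gene, rose by 1.87 ± 0.34 (adjusted p = 0.0123), while BT2 and AT3G15450 fell, with -2.36 ± 0.37 (adjusted p = 0.00466) and -2.16 ± 0.29 (adjusted p = 0.0018). By the labels, 9 of the genes named here had the other direction: SIGE -0.12, HY5 -0.56, AT5G64170 -0.0019, PCL1 -0.65, PRR9 -0.21, GI -0.22, STZ -0.30, BT2 0.27 and AT3G15450 0.43. In all, by the file names, 116 genes passed, 96 higher and 20 lower, against 186 with DESeq2 and 363 without the filter on low counts. The count was 15 without flu/ex1 30 min replicate 3, 25 without flu/ex1 60 min replicate 1 and 45 without flu/ex1 0 min replicate 2. It was 56 without flu/ex1 0 min replicate 3, 176 without flu/ex1/ydl1 60 min replicate 2 and 181 without flu/ex1/ydl1 30 min replicate 1.

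By the file names at 60 min in flu/ex1, of light-induced genes 9 of 15 (11 adjusted over the list alone) had risen (camera adjusted p = 2.82e-19, adjusted p = 0.00956 with an estimated correlation). ELIP1 stood at 137 ± 18.5 against 18.3 ± 3.37 CPM (SD, n = 2 each), a log2 fold change of 2.90 ± 0.28 (SE) with an adjusted p of 0.000181. F3H, a flavonoid synthesis gene, rose by 2.38 ± 0.33 (adjusted p = 0.00168) on the log2 scale, PRR9 by at least 14.1-fold from 0 counts (a log2 fold change of -0.37 by the labels), and the clock gene RVE2 had -1.41 ± 0.31 (adjusted p = 0.0338). Of singlet oxygen-responsive genes 1 of 17 (3 adjusted over the list alone) rose, STZ by 1.52 ± 0.35 (camera adjusted p = 0.0101 for the list, adjusted p = 0.55 with an estimated correlation). A few members of other lists rose: OPR3, of jasmonate synthesis, by 1.57 ± 0.33, MBF1C, of the heat response, by 2.06 ± 0.48, AOX1A, the mitochondrial alternative oxidase gene, by 2.33 ± 0.42, CAT2, a catalase gene, by 1.70 ± 0.33 and NCED3 by 1.94 ± 0.33. The jasmonate-response gene ORA59 and the shade-induced gene PAR1 fell, with -2.34 ± 0.48 (adjusted p = 0.0224) and -1.50 ± 0.32 (adjusted p = 0.0268). In all 246 genes passed, 185 higher and 61 lower, against 701 without the filter on low counts. The count was 56 without flu/ex1 0 min replicate 2, 87 without flu/ex1 30 min replicate 2 and 100 without flu/ex1 30 min replicate 3. It was 103 without flu/ex1 60 min replicate 3.

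The same comparisons in flu/ex1/ydl1 ask what light changes once YDL1 is mutated as well. By the labels no gene passed at 30 min with edgeR, where MBF1A had 1.56 ± 0.31 (adjusted p = 0.798), ATMG00665 -1.10 ± 0.23 (adjusted p = 0.798) and AT1G48315 1.74 ± 0.36 (adjusted p = 0.798). Of all genes 1070 had an unadjusted p under 0.05, DESeq2 called 0, edgeR without the filter on low counts 359 and edgeR on only the groups compared 0. The edgeR count was 2 without flu/ex1/ydl1 30 min replicate 3. By the labels no gene passed at 60 min with edgeR, where LEA4-5 had 5.52 ± 1.15 (adjusted p = 0.892), AT1G35115 3.33 ± 0.76 (adjusted p = 0.892) and AT1G55630 3.78 ± 0.88 (adjusted p = 0.892). Of all genes 762 had an unadjusted p under 0.05, DESeq2 called 0, edgeR without the filter on low counts 426 and edgeR on only the groups compared 0. The 17 singlet oxygen-responsive genes had a median of 1.38 at 60 min by the labels, with 0 passing either over all genes or adjusted over the list alone (camera adjusted p = 1.54e-07, adjusted p = 0.505 with an estimated correlation).

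By the file names, the singlet oxygen-responsive genes rose in flu/ex1/ydl1 within 30 min. Of these genes 15 of 17 (17 adjusted over the list alone) rose, with a median of 3.20 (camera adjusted p = 3.99e-26, adjusted p = 0.0948 with an estimated correlation). ERF6 stood at 78.9 ± 17.7 against 2.8 ± 0.258 CPM (SD, n = 2 each), a log2 fold change of 4.81 ± 0.52 (SE) with an adjusted p of 2.42e-05. STZ rose by 3.34 ± 0.36 (adjusted p = 2.42e-05), MPK3 by 3.09 ± 0.33 (adjusted p = 2.29e-05), FC1 by 3.03 ± 0.30 (adjusted p = 1.34e-05), NCED3 by 3.41 ± 0.33 (adjusted p = 1.34e-05) and SIGE by 2.80 ± 0.38 (adjusted p = 0.000163) on the log2 scale. Of touch, wounding and calcium genes 8 of 14 (12 adjusted over the list alone) rose (adjusted p = 0.0948 with an estimated correlation). Among the largest rises were AT1G05767, at least 39.5-fold, TDR1, at least 31.7-fold, and MC8, a metacaspase gene, at least 25.3-fold, each from 0 counts at 0 min. The auxin-related gene SAUR29 fell, with -2.30 ± 0.47 (adjusted p = 0.00494), against 0.42 by the labels. In all 964 genes passed, 857 higher and 107 lower. The count was 438 without flu/ex1/ydl1 30 min replicate 3, 505 without flu/ex1/ydl1 60 min replicate 1 and 578 without flu/ex1/ydl1 0 min replicate 1.

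By the file names at 60 min in flu/ex1/ydl1, 2283 genes had passed, 1717 higher and 566 lower. All 17 of 17 tested singlet oxygen-responsive genes rose, with a median of 3.88 (camera adjusted p = 2.79e-22, adjusted p = 0.0443 with an estimated correlation). STZ stood at 156 ± 46.3 against 10.6 ± 1.86 CPM (SD, n = 2 each), a log2 fold change of 3.88 ± 0.36 (SE) with an adjusted p of 2.47e-06. WRKY33 rose by 4.46 ± 0.44 (adjusted p = 3.52e-06), ERF6 by 5.06 ± 0.52 (adjusted p = 5.24e-06), LOX4 by 4.57 ± 0.43 (adjusted p = 2.47e-06), AOX1A by 5.32 ± 0.45 (adjusted p = 1.25e-06), HSP101 by 4.43 ± 0.49 (adjusted p = 9.37e-06) and NCED3 by 4.22 ± 0.33 (adjusted p = 1.1e-06) on the log2 scale. All 10 of 10 heat shock genes rose, with a median of 4.33 when HSP17.6II, at 0 counts in the dark, is taken at its bound. Of jasmonate genes 16 of 21 (16 adjusted over the list alone) rose, as did 10 of 13 (11) salicylate, 16 of 22 (16) antioxidant, 12 of 14 (12) touch and 6 of 14 (6) abscisic acid genes. Of light-induced genes 6 of 15 (7 adjusted over the list alone) rose, and of clock genes 6 of 17 rose and 1 fell, with 8 rising and 1 falling adjusted over the list alone. Each of these lists had adjusted p = 0.0443 with an estimated correlation. In tetrapyrrole synthesis FC1 rose by 3.39 ± 0.30, HEMA2 by 2.78 ± 0.35 and HEMA1 by 0.89 ± 0.26, while none of 20 light harvesting and none of 3 root marker genes passed. Of 13 genes induced in darkness and starvation, DIN11 and DIN9 rose, by 3.84 ± 0.77 and 1.79 ± 0.54. Of 3 shade genes PAR1 and FHY1, a factor of phytochrome signalling, fell, with -1.97 ± 0.36 and -1.83 ± 0.45. TDR1 rose at least 169-fold and AT4G12735 at least 74.1-fold from 0 counts, while SAUR29 had -2.96 ± 0.51 and the auxin-related AT4G38860 -2.67 ± 0.26. The count was 1427 without flu/ex1/ydl1 30 min replicate 3 and 1512 without flu/ex1/ydl1 0 min replicate 1.

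**Figure D3:**
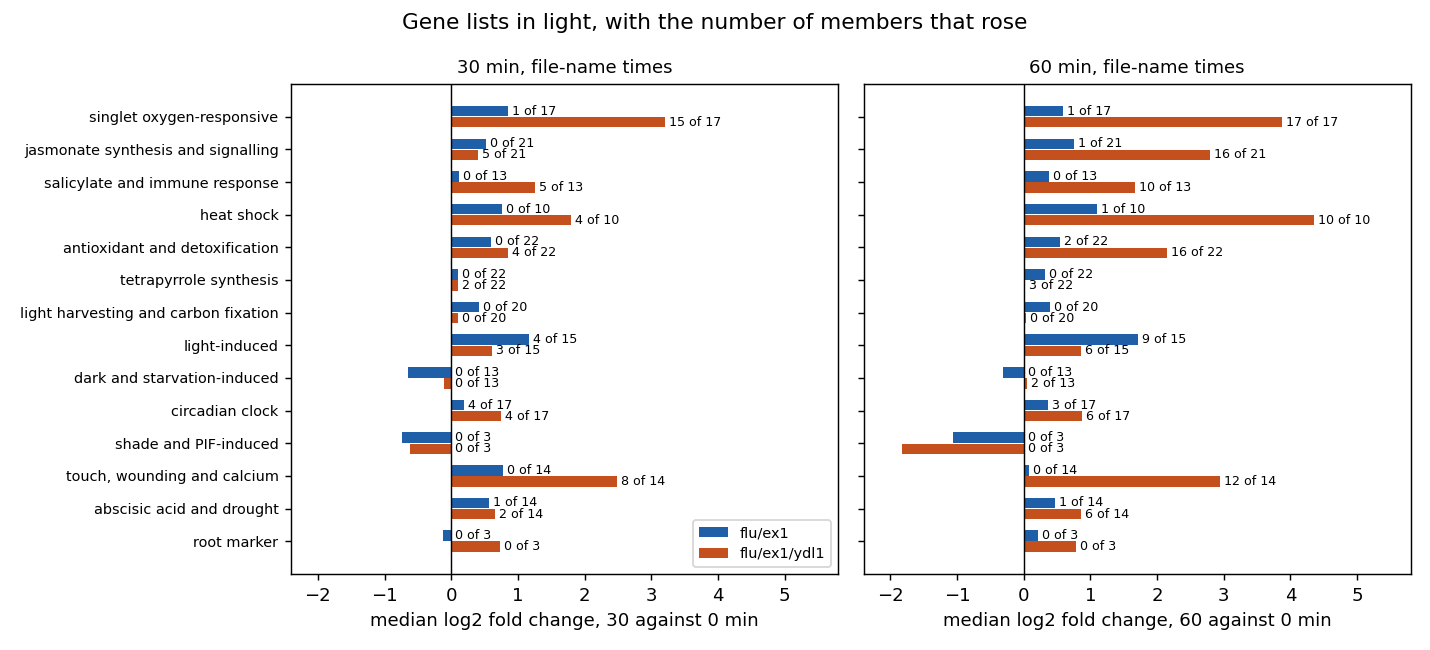
Bars give the median log2 fold change of each of 14 gene lists at 30 min (left) and 60 min (right) against 0 min by file-name time, in flu/ex1 (blue) and flu/ex1/ydl1 (orange), and the text at each bar gives the number of members that rose. At 60 min 1 of 17 singlet oxygen-responsive genes rose in flu/ex1 and 17 of 17 in flu/ex1/ydl1.

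The difference between the genotypes in their change in light asks directly whether the ydl1 mutation alters the response. By the labels no gene passed with edgeR for the change to 30 min, where AT3G41768 had 7.99 ± 1.79 (adjusted p = 1), AT1G69070 1.68 ± 0.39 (adjusted p = 1) and AT3G55646 3.62 ± 0.86 (adjusted p = 1). Of all genes 481 had an unadjusted p under 0.05, DESeq2 called 0, edgeR without the filter on low counts 64 and edgeR on only the groups compared 0. By the labels no gene passed with edgeR for the change to 60 min, where ZF3 had 3.02 ± 0.54 (adjusted p = 0.804), AT1G61260 2.55 ± 0.52 (adjusted p = 0.804) and AT1G70750 2.31 ± 0.48 (adjusted p = 0.804). Of all genes 1065 had an unadjusted p under 0.05, DESeq2 called 0, edgeR without the filter on low counts 256 and edgeR on only the groups compared 6. The edgeR count was 1 without flu/ex1 0 min replicate 3. The 17 singlet oxygen-responsive genes had a median difference of 1.76 to 60 min, with 0 passing (camera adjusted p = 9.72e-05, adjusted p = 0.674 with an estimated correlation).

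By the file names, the singlet oxygen-responsive genes changed more to 60 min in flu/ex1/ydl1 than in flu/ex1. Of these genes 15 of 17 (17 adjusted over the list alone) rose more in flu/ex1/ydl1, with a median of 3.56 on the log2 scale (camera adjusted p = 6.32e-21, adjusted p = 0.141 with an estimated correlation, fry adjusted p = 0.0568). PFA-DSP3 rose more by 4.43 ± 0.59 (adjusted p = 0.0012), ERF6 by 4.07 ± 0.80 (adjusted p = 0.0086) and WRKY33 by 3.56 ± 0.59 (adjusted p = 0.0031), where n = 2 for each of the 4 groups. So did 6 of 21 (12 adjusted over the list alone) jasmonate, 3 of 13 (8) salicylate, 4 of 10 (6) heat shock, 3 of 22 (3) antioxidant and 6 of 14 (9) touch genes, among them MPK3 by 3.26 ± 0.44 (adjusted p = 0.0012). The camera calls of these lists had adjusted p = 0.141, 0.141, 0.163, 0.141 and 0.141 with an estimated correlation. FC1 rose more by 2.97 ± 0.40 (adjusted p = 0.0012), HEMA2 by 3.01 ± 0.50 (adjusted p = 0.00338) and NCED3 by 2.28 ± 0.50 (adjusted p = 0.0155), and TT5, a flavonoid synthesis gene of the light-induced list, had -1.56 ± 0.35 (adjusted p = 0.0197). FC1 and HEMA2 are not typical of the tetrapyrrole list. In the 4 libraries with 1 time in both, 17 of its 22 genes had a lower change in flu/ex1/ydl1 and 5 a higher one (median -0.53, no test). In all 582 genes passed, 557 with a higher and 25 with a lower change in flu/ex1/ydl1, against 885 without the filter on low counts and 334 with the file-name replicate block. The count was 230 without flu/ex1/ydl1 30 min replicate 3, 251 without flu/ex1 60 min replicate 3 and 345 without flu/ex1 0 min replicate 2. It was 366 without flu/ex1 30 min replicate 3 and 373 without flu/ex1/ydl1 0 min replicate 1. PP2-B13 and PP2-B14, of one gene family, and their neighbour AT1G56242 were among the largest differences, and how reads that map to several loci were treated is not stated.

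By the file names, 21 genes passed for the difference in the change to 30 min, all with a higher change in flu/ex1/ydl1. The receptor-like kinase gene CRK11 had 2.83 ± 0.51 (adjusted p = 0.0416), the calcium-dependent protein kinase gene CPK28 2.63 ± 0.49 (adjusted p = 0.0469), MPK3 2.61 ± 0.44 (adjusted p = 0.0416), NADK1 2.65 ± 0.46 (adjusted p = 0.0416), CAD1 2.52 ± 0.39 (adjusted p = 0.0416) and FC1 2.25 ± 0.40 (adjusted p = 0.0416). Of singlet oxygen-responsive genes 0 of 17 (15 adjusted over the list alone) were higher (camera adjusted p = 3.25e-12, adjusted p = 0.285 with an estimated correlation). DESeq2 called 129 genes, edgeR without the filter on low counts 300 and edgeR with the file-name replicate block 41. The count was 0 without flu/ex1 0 min replicates 2 or 3, flu/ex1 30 min replicate 3, flu/ex1 60 min replicates 1 or 3, flu/ex1/ydl1 0 min replicates 1 or 3, flu/ex1/ydl1 30 min replicate 3 or flu/ex1/ydl1 60 min replicate 1 and 46 without flu/ex1/ydl1 30 min replicate 1 or flu/ex1/ydl1 60 min replicate 2.

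The 4 libraries whose labelled and file-name times are the same leave 1 library per genotype at 0 and at 60 min, so no replicates and no test. CPM here were scaled on these 4 libraries alone, so they differ somewhat from the CPM given elsewhere. In these libraries ERF6 stood at 2.05 CPM at 0 min and 1.03 CPM at 60 min in flu/ex1, and at 2.77 and 67 CPM in flu/ex1/ydl1. The 17 singlet oxygen-responsive genes had a median log2 difference between 60 and 0 min of -0.85 in flu/ex1 and 3.37 in flu/ex1/ydl1. Among 10000 random lists of as many genes of like level, the former lay at percentile 0, with 11 of 17 lower, and the latter at percentile 100, with 17 of 17 higher. The fall in flu/ex1 goes against the median of 0.59 over all libraries by file-name time. That fall rests on 1 library at each time, flu/ex1 60 min replicate 3 and flu/ex1 0 min replicate 2. The latter had 0.828% of its counts on ribosomal RNA loci. Which of the 2 libraries brings the fall was not tested. These percentiles compare genes within 1 library per group and carry no spread between libraries. The 15 light-induced genes had medians of 1.84 in flu/ex1 and 1.08 in flu/ex1/ydl1, and the 10 heat shock genes -0.17 and 2.82. Differences of more than 4-fold upward were seen in 177 genes in flu/ex1 and 857 in flu/ex1/ydl1, and downward in 146 and 171.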

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

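The tests of the neighbouring loci, and those with thinned libraries or with nuclear genes only under file-name times, were chosen after the result was seen. Of 16 groups of 6 libraries examined for a library far from the rest, 2 had one, and chance gives about 5% of groups. The share of counts on ribosomal RNA loci was 0.828% in flu/ex1 0 min replicate 2, against 0.0439% in the next library of that genotype. EX1 stood at 2.91 CPM in the same library, against 4.41 CPM in the next. With times from the file names, the change from 0 to 30 min differed between genotypes in 21 genes and the change from 0 to 60 min in 582.

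The labelled light times and those in the file names differ for 8 of 12 libraries. A difference in depth as the source of the resemblance is argued against, since after thinning to one nuclear depth the share of pairings as close as that by file-name time was again 0.00889. A candidate explanation is that deposited files were attached to samples of another time, since a share of 0.00889 of all pairings was as close as that by file-name time and 0.564 as close as that by labelled time. Within flu/ex1 alone 2 of 15 pairings were as close as that by file-name time, itself included, and within flu/ex1/ydl1 1 of 15. Over all genes kept by the filter these were 1 and 1 of 15. The shares of 0.00889 and 0.564 argue against the labelled times for the 12 libraries as a set. They compare pairs of libraries and do not by themselves say which pair belongs to which time. In each genotype, 1 file-name pair holds the library with 0 min in both records. Another holds the library with 60 min in both. No biological explanation was tested, and neither record itself says which set of times is right.

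With file-name times the change from 0 to 60 min was larger in flu/ex1/ydl1 for 557 of the 582 genes. The pattern does not need the plastid and mitochondrial counts, since 591 genes passed with nuclear genes only. TMM scaling was already used with all genes, so this says little about a difference in the share of those counts. A difference in depth between libraries is argued against, since 521 passed after thinning. With the file-name replicate block 334 passed. The ydl1 mutation, which the design names, stays open as a biological explanation, and the pattern rests on the grouping by file-name time. Other differences between the 2 genotypes cannot be told apart from that mutation here. In flu/ex1/ydl1 6 loci were under 5% of flu/ex1, among them GID1B (3 counts against 248) and MRD1 (10 against 438). In the opposite direction there were 15. Whether the low counts come with the ydl1 mutation is not known. With labelled times 0 genes passed with edgeR, with 1065 genes at an unadjusted p under 0.05. DESeq2 called 0, edgeR without the filter on low counts 256 and edgeR on only the groups compared 6.

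On chromosome 3, 4 neighbouring detected loci were near zero in all 6 flu/ex1/ydl1 libraries together: GID1B with 3 counts against 248, MBD4 with 1 against 57, AT3G63052 with 189 against 22038 and EDL3 with 0 against 27. A lower depth in flu/ex1/ydl1 is argued against, since the unscaled counts of the 19701 detected loci had a median of 75.6% of flu/ex1, against at most 1.75% for the 4 loci. A deletion or other structural change over these loci is a candidate explanation, since the run of 4 loci under 5% was longer than the longest run of 2 in 10000 shuffles of the ratios of 19701 detected loci, a p of 1e-04, the smallest the shuffles can give. In the opposite direction a run of 3 loci, PP2-B13, AT1G56242 and PP2-B14, was under 5% in flu/ex1, also longer than the longest run of 2 in 10000 shuffles. These 3 loci had 92, 67 and 36 counts in flu/ex1, and their low ratio comes from a rise in flu/ex1/ydl1. In the 4 libraries with 1 time in both, scaled on these alone, PP2-B14 stood at 0.639 CPM in flu/ex1 and 0.378 CPM in flu/ex1/ydl1 at 0 min. At 60 min it stood at 0.115 and 28.6 CPM. The counts of 189 on AT3G63052 keep a loss of transcription, or a segment brought in with the ydl1 mutation from another strain, open as well. Whether this stretch holds YDL1 is not known, as the reference names no such locus.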

How the results depend on the processing

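The alternatives with file-name times, the thinning and the 4 libraries with 1 time in both were chosen after the result was seen. With labelled times the counts of genes were 6 for genotype over 12 libraries, 2 for genotype at 0 min, 0 for genotype at 30 min, 0 for genotype at 60 min, 0 for 30 min of light in flu/ex1, 0 for 60 min in flu/ex1, 0 for 30 min in flu/ex1/ydl1, 0 for 60 min in flu/ex1/ydl1, 0 for the difference to 30 min and 0 for the difference to 60 min. They were within 1.5 times of this with DESeq2's size factors in edgeR and with nuclear genes only. With DESeq2 they became 774 for genotype over 12 libraries, 4 for genotype at 0 min, 2 for genotype at 30 min, 312 for genotype at 60 min and 6 for 60 min in flu/ex1. With no filter they became 1813 for genotype over 12 libraries, 166 for genotype at 0 min, 833 for genotype at 30 min, 1537 for genotype at 60 min, 23 for 30 min of light in flu/ex1, 90 for 60 min in flu/ex1, 359 for 30 min in flu/ex1/ydl1, 426 for 60 min in flu/ex1/ydl1, 64 for the difference to 30 min and 256 for the difference to 60 min, where edgeR's prior degrees of freedom went from 5.17 to infinite, so that each gene was given the spread of the trend. Fitting only the groups compared gave 1 for genotype at 0 min, 1511 for genotype at 60 min, 52 for 60 min in flu/ex1 and 6 for the difference to 60 min, and genotype alone gave 747 for genotype over 12 libraries. Replicate numbers as a block gave 1 for genotype over 12 libraries and 0 for genotype at 0 min. Of 19 same-number pairs 6 had a correlation above 0.1 (range -0.521 to 0.446), taken on deviations from the means of the labelled groups. If the labelled times are wrong, these deviations carry differences in time. They therefore cannot decide whether the numbers pair the libraries. Leaving out 1 library gave 3 to 1633 for genotype over 12 libraries, 0 to 2 for genotype at 0 min, 0 to 830 for genotype at 30 min, 0 to 930 for genotype at 60 min, 0 to 0 for 30 min of light in flu/ex1, 0 to 1 for 60 min in flu/ex1, 0 to 2 for 30 min in flu/ex1/ydl1, 0 to 0 for 60 min in flu/ex1/ydl1, 0 to 0 for the difference to 30 min and 0 to 1 for the difference to 60 min. File-name times gave 1604 for genotype over 12 libraries, 700 for genotype at 30 min, 1763 for genotype at 60 min, 116 for 30 min of light in flu/ex1, 246 for 60 min in flu/ex1, 964 for 30 min in flu/ex1/ydl1, 2283 for 60 min in flu/ex1/ydl1, 21 for the difference to 30 min and 582 for the difference to 60 min. The cause was not tested, except for the filter and, on simulated counts, the grouping by time. There 4-fold changes that followed the file names were recovered for 97% of genes with file-name groups and 2% with labelled groups.

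With file-name times the counts were 1604 for genotype over 12 libraries, 2 for genotype at 0 min, 700 for genotype at 30 min, 1763 for genotype at 60 min, 116 for 30 min of light in flu/ex1, 246 for 60 min in flu/ex1, 964 for 30 min in flu/ex1/ydl1, 2283 for 60 min in flu/ex1/ydl1, 21 for the difference to 30 min and 582 for the difference to 60 min. They stayed within 1.5 times of this with nuclear genes only, with DESeq2's size factors in edgeR and after thinning. DESeq2 gave 186 for 30 min of light in flu/ex1 and 129 for the difference to 30 min. No filter gave 10 for genotype at 0 min, 363 for 30 min of light in flu/ex1, 701 for 60 min in flu/ex1, 300 for the difference to 30 min and 885 for the difference to 60 min, and the file-name replicate block 1 for genotype at 0 min, 41 for the difference to 30 min and 334 for the difference to 60 min. Of 19 same-number pairs 6 had a correlation above 0.1. Leaving out 1 library gave 1023 to 2193 for genotype over 12 libraries, 0 to 4 for genotype at 0 min, 121 to 811 for genotype at 30 min, 942 to 1894 for genotype at 60 min, 15 to 181 for 30 min of light in flu/ex1, 56 to 363 for 60 min in flu/ex1, 438 to 1092 for 30 min in flu/ex1/ydl1, 1427 to 2419 for 60 min in flu/ex1/ydl1, 0 to 46 for the difference to 30 min and 230 to 710 for the difference to 60 min. Camera called 42 lists over the comparisons with labelled times, 0 with an estimated correlation and 0 with fry, and 74, 12 and 38 with file-name times. The cause was not tested, except for the filter, without which the prior degrees of freedom went from 10.8 to infinite.

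Among 387 values for named genes, not each of which every alternative gives, 368 kept their side of the threshold with DESeq2, 386 without the filter and 356 after thinning, and 0 changed direction under these. Without 1 library, 3987 values kept it and 657 did not, with 0 in the other direction. With DESeq2's size factors 382 kept it, with nuclear genes only 385 and with the file-name replicate block 341. With labelled times 342 of the values called with file-name times no longer passed, 5 passed and 32 changed direction. The log2 fold changes of the latter with labelled times were as follows. For 30 against 0 min of light in flu/ex1 they were PRR9 -0.21, PUB19 -0.11, BBX31 -0.86, BBX30 -0.97, GI -0.22, PAP17 -0.45, AT3G29000 -1.22, AT2G46940 -0.93, BT2 0.27, AT5G61590 0.94, AT3G15450 0.43, AT5G22920 0.54, AT1G23390 1.02, ACHT5 0.037, BZIP61 0.075, ATCTH 1.43, STZ -0.30, SIGE -0.12, HY5 -0.56, AT5G64170 -0.0019, PCL1 -0.65. For 60 against 0 min of light in flu/ex1 they were PRR9 -0.37. For 30 against 0 min of light in flu/ex1/ydl1 they were AT1G02610 1.44, AT1G08710 0.78, AT5G02515 0.39, AT3G02725 0.15, AT1G29460 0.71, XTH11 0.018, SAUR29 0.42, F3H -0.52, PCL1 -0.012, MKK9 -0.14. The cause was not tested. Thinning to the lowest nuclear count left the counts of genes with file-name times within 1.5 times, and lower depths were not tested. With 2 libraries per group, simulated changes of 2-fold in 60 against 0 min in flu/ex1/ydl1 were called for 29% of genes, and depth was not varied there. The spread in that simulation came from the file-name groups.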

Other observations

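The count of loci near zero and the test of the smallest p over splits were chosen after the result was seen. With file-name times ATSDI1, a gene induced by sulfur deficiency, was lower in flu/ex1/ydl1 over the 12 libraries, with a log2 fold change of -1.98 ± 0.23 (adjusted p = 2.55e-05), as was CGA1, a GATA factor gene of chloroplast development, with -1.37 ± 0.20 (adjusted p = 0.000249). In flu/ex1/ydl1 at 60 min by the file names, the auxin-related neighbours AT1G29430, AT1G29450 and AT1G29460 had log2 fold changes of -2.72 ± 0.46 (adjusted p = 0.000527), -2.80 ± 0.54 (adjusted p = 0.00148) and -2.94 ± 0.71 (adjusted p = 0.00945). They belong to one family, and reads shared among them are possible. In flu/ex1 at 30 min by the file names, BBX30 and BBX31, of a family of light-signalling zinc finger genes, rose by 3.96 ± 0.53 (adjusted p = 0.0018) and 4.16 ± 0.53 (adjusted p = 0.00106), while by the labels they had -0.97 and -0.86.

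MRD1 had 10 counts in flu/ex1/ydl1 against 438 in flu/ex1 and AT3G58820 had 2 against 55. With the 4 neighbours on chromosome 3 these were the loci under 5% of flu/ex1 among 19701 detected. In the opposite direction 15 loci were under 5% in flu/ex1.

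Other splits of the 12 libraries swapped libraries between genotypes within a time. With labelled times 7 of 100 splits gave 6 genes or more, the real one included, so chance cannot be excluded for the number of genes, and the highest other split gave 1118 genes. That split swaps 2 libraries of each genotype. It calls many times the real count, which points to a structure of the samples. Its swaps lie at labelled 0 and 30 min, the labelled times of all libraries with a file-name time of 0 min. Whether file-name time is that structure was not tested. For the gene with the smallest p by labelled times chance is argued against but not excluded, since 1 of 100 is the smallest share the splits can give. That p, of AT3G63052, was 4.65e-08, with 4.17 ± 3.57 against 356 ± 141 CPM (SD, n = 6 each), and 1 of 100 splits, the real one, had a smallest p over all genes as small. The lowest of the others was 7.87e-08. With file-name times 2 of 100 splits, the real one included, had a smallest p as small as the real 1.86e-11, and the lowest of the others was smaller, at 6.35e-12. With file-name times 2 of 100 splits gave 1604 genes or more, the real one included, a share of 0.02. Chance is argued against for the number of genes but not excluded, since another split gave more genes than the real one. That split, which swaps 1 library of each genotype at 0 min, gave 2345.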
